A study of Mus musculus with 8 samples.

How the data were processed

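Total RNA from mouse skin was sequenced in 8 libraries, 1 for each of 2 genotypes (wildtype and hairloss) at each of postnatal days 0, 16, 19 and 28. Groups and ages come from the sample labels. RNA was isolated with RNeasy columns and libraries were made with TruSeq kits, per the labels' protocols. The number of animals behind a library, and whether libraries kept strand information, are not given in the sources used here. Cutadapt, Cuffdiff and the mouse build mm10 are named, without versions, per the submitters' processing notes. The aligner and the annotation release are not given in the sources used here.

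The authors deposited, for each library, 1 value per Ensembl gene, with no unit in the header. The deposited values were taken to be FPKM, an inference from the values and from Cuffdiff being named per the submitters' processing notes. They are not whole, their totals per library differ (1080978 to 2501651), and short RNA genes hold the highest values, 57.7% to 77.7% of the total. Whether Cuffdiff scaled the libraries to each other is not given in the sources used here. FPKM divides by transcript length, so the values of very short genes are large and unstable. Symbols were taken from the files for 21795 genes and from GENCODE M21, which is on the same build, for 33387 others, and 236 stayed without a symbol. Coordinates and gene types also come from GENCODE M21. The files hold no counts, so tests for counts were not used.

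The depth of each library was estimated from genes with a single annotated transcript of more than 1000 bases, as the depth at which the most genes carry the value of 1 fragment. This gave 36300000, 31600000, 38000000 and 36300000 fragments for wildtype at days 0, 16, 19 and 28, and 36300000, 43700000, 31600000 and 43700000 for hairloss. It is an estimate from the values, and floors of 3 fragments drawn from it cover counting error only. An exact 0 can be a failed estimate. For that reason 90 genes with a 0 in some but not most libraries and at least 5 FPKM in every library above 0 were treated as suspected failed estimates, 9 of them protein-coding, and an alternative left them out. The set includes the Y-linked genes Ddx3y and Uty, whose 0 can also be an absence of male RNA. Genes named as listed at 0 are given by library and without a fold.

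Values were analysed as log2(FPKM + 1), which understates the fold of low genes. At each age the 2 libraries were compared by a size rule of at least 2-fold on this scale and at least 1 FPKM in either library, with no test because there is 1 library per group. Before the data were examined, 50 gene lists were fixed, of which 49 had at least 3 measured genes. A list's median difference at an age is given with its percentile among 10000 random lists of equal size matched on mean expression in 20 bins. The genotype difference over ages was tested with limma (version 3.58.1 in R 4.3.3, eBayes with trend and robust) with age as a 4-level block, over 18724 genes of at least 1 FPKM in some library. That leaves 3 residual degrees of freedom, and the spread it uses is that of the difference over ages, which also holds any real change of the difference with age. Age steps were tested with the same tool with genotype as a block. All tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists were tested over ages with camera at a preset correlation of 0.01, and with camera at an estimated correlation and fry beside it. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

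Genes named in the text were chosen by a rule fixed before the data were examined. At each age these were the 10 genes with the largest difference in each direction, and up to 4 members with the largest difference of each list described. Over the 4 ages they were up to 10 genes in each direction with the largest mean difference among those past the threshold and moving the same way at all ages, or, where fewer passed, among those moving the same way. For the age steps they were up to 5 genes each way past the threshold with the same direction in both genotypes, and list members as above. Predicted genes and small RNAs were not named, and genes known for hair loss in mice and sex-linked genes could always be named. Exceptions, where a small count had to be resolved into genes, are said in the text to be chosen after their values were seen, and members given as the only ones past 2-fold in a list were chosen in the same way.

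The genotype test, the test of the day 28 step and the list percentiles of day 19 were tried on simulated data. Of genes changed by 2, 4, 8 and 32-fold, the genotype test over 18724 genes recovered 72%, 86%, 96% and 98%, with 7 false calls among 183, and the test of the day 28 step recovered 26%, 92%, 94% and 100%, with 11 false calls among 167. The changed genes were drawn from the more highly expressed ones. Each was shifted equally at every age, or in both genotypes for the day 28 step, with independent noise. These shares therefore do not carry over to low genes or to differences that vary with age or genotype. Of 1000 random lists with no added change 6.2% lay in the outer 5% of the list percentiles, and 20 of 20 lists shifted by 1.5 lay above the upper limit. Both kinds of list held randomly drawn genes, so this checks the ranking and not lists whose members vary together. The control list of housekeeping genes lay at percentile 99.25 at day 16, so an extreme percentile does not measure how rare such a list is.

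Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter on low values, a filter at 5 FPKM, median-of-ratios scaling, scaling on genes outside the keratin and KRTAP families, a size rule of 4-fold, limma without trend and robust, fits without the block, each age left out in turn, and an estimated correlation. Chosen after seeing the data were protein-coding genes only, autosomal genes only, suspected failed estimates left out, and fits without days 0 and 28, where the hairloss libraries lack Y-linked RNA. A change in a list median was called a move when it exceeded the standard deviation over the list's members. All 8 libraries were used.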

Results

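Skin RNA was sequenced from wildtype mice and from mice that the labels call hairloss, which carry a spontaneous mutation. Skin was taken at postnatal days 0, 16, 19 and 28, giving 8 libraries with 1 library per genotype and age. No group was replicated, so a difference between the genotypes at a single age has no error of its own and describes those 2 libraries. The question named in the series title is how keratin genes and genes of keratin-associated proteins differ in the mutated mice. Each library was deposited as 1 value per Ensembl gene, read as FPKM, a count of fragments scaled to transcript length and library size. The spacing of the lowest values implied 31600000 to 43700000 fragments per library, at which 3 fragments in a transcript of 1 kb correspond to 0.069 to 0.095 FPKM, counting error only. Markers of sex matched between the genotypes at day 16 alone. Ddx3y, a Y-linked gene, stood at 16.3 FPKM in the wildtype and 0 in the hairloss library of day 0, at 20.1 and 20.4 FPKM at day 16, at 15.8 and 19.4 FPKM at day 19, and at 16.5 and 0 FPKM at day 28. Xist, which is transcribed from the inactive X chromosome, stood at 51.3, 0.0158, 12.4 and 0.166 FPKM in the wildtype libraries of days 0, 16, 19 and 28, and at 76.1, 0.00961, 0.115 and 50.1 FPKM in the hairloss libraries. The wildtype libraries of days 0 and 19 therefore held both Y-linked RNA and Xist RNA. Several genes that skin expresses strongly were listed at exactly 0 in some libraries, among them Col1a1 and Col3a1, and such a 0 can be a failed estimate.

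Hair shaft keratins, the intermediate filament proteins of the hair fibre, were lower in the hairloss library than in the wildtype library at day 16, higher at day 19, and lower again at day 28. Their median level over 15 genes was 313 FPKM in wildtype and 80.7 FPKM in hairloss skin at day 16, 2.17 and 30.8 FPKM at day 19, and 343 and 0.060 FPKM at day 28. Keratin-associated proteins (KRTAPs), which cross-link the keratin filaments of the hair shaft, followed the same order, with medians over 57 genes of 176 and 32.3 FPKM, then 1.54 and 15.6 FPKM, then 135 and 0 FPKM. Together the keratin and KRTAP genes held 10.5% of the FPKM of coding genes in wildtype and 6.16% in hairloss skin at day 16, 1.58% and 4.92% at day 19, and 8.10% and 2.73% at day 28. At day 0 the shares were 1.53% and 2.25%.

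**Figure D1:**
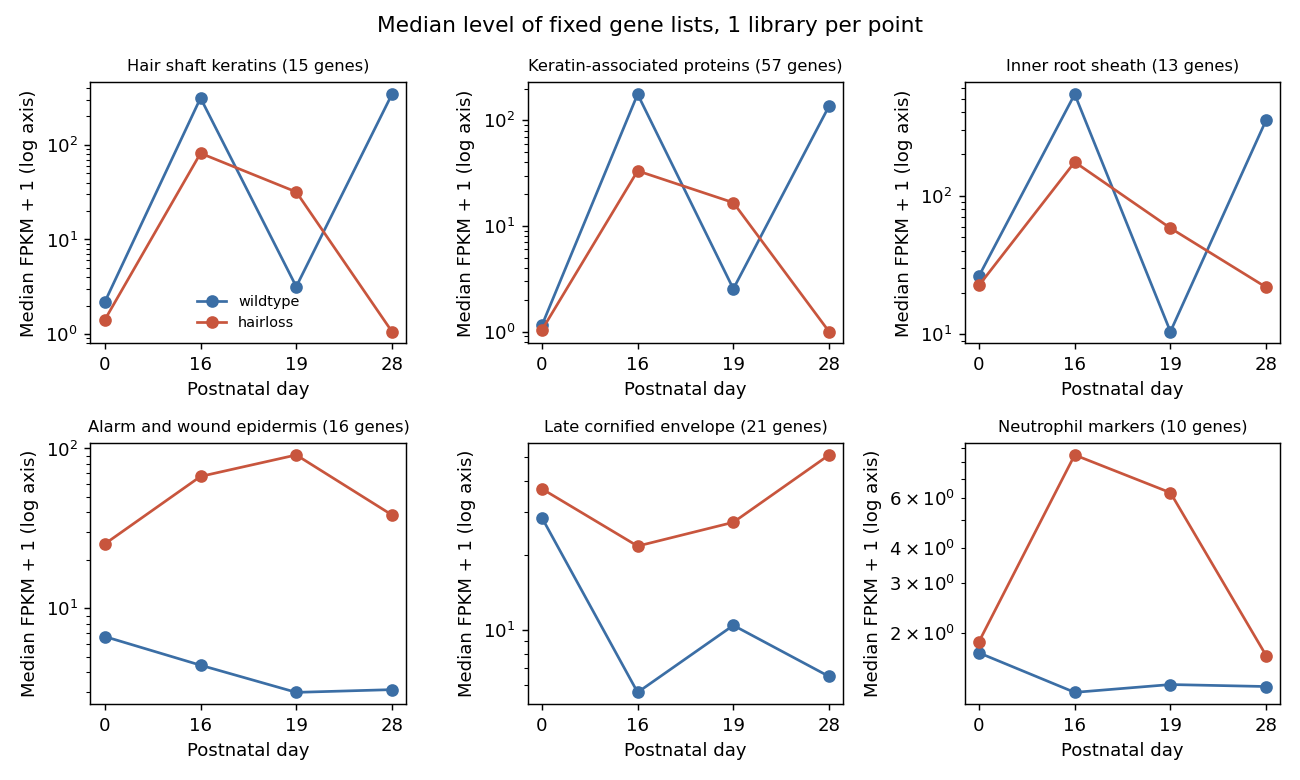
Median level of 6 gene lists at postnatal days 0, 16, 19 and 28, with days spaced evenly on the horizontal axis and FPKM + 1 on a logarithmic vertical axis; each point is 1 library, blue for wildtype and red for hairloss. Hair shaft keratins stood at 343 FPKM in wildtype and 0.060 FPKM in hairloss skin at day 28, while the alarm and wound epidermis list was higher in the hairloss library at each of the 4 ages.

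At day 0 the skin of the genotypes was most alike. Krt6b (chromosome 15, 101676023 to 101680287, build mm10), a keratin of the outer root sheath companion layer and of wounded epidermis, stood at 5.48 FPKM in wildtype and 100.5 FPKM in the hairloss library. Krt16, induced with it in wounds, stood at 48.2 and 98.0 FPKM, and Krt6a at 5.77 and 22.6 FPKM. Repetin, encoded by Rptn and part of the cornified envelope, stood at 15.7 and 154 FPKM, and Sprr2d, a small proline-rich envelope precursor, at 12.5 and 62.2 FPKM. Lower in the hairloss library were Cyp2b19, a cytochrome P450 of keratinocytes, at 54.8 against 6.54 FPKM, and Ucp1, the uncoupling protein of brown fat, at 100.7 against 3.25 FPKM. Among the gene lists, alarmins and wound-type epidermal genes had a median difference of 0.53 on the log2(FPKM + 1) scale, with 6 of 16 members at least 2-fold higher and 0 lower, at percentile 100 of 10000 random lists matched on expression. Late cornified envelope genes, which form the outer barrier of the epidermis, had a median of 0.65, with Lce1k alone among 21 members past 2-fold. None of the 15 hair shaft keratins differed 2-fold on the log2(FPKM + 1) scale, which narrows differences of low genes, and their median was -0.41, at percentile 0, or -0.92 with a pseudocount of 0.1. Krt86 stood at 0.625 FPKM in wildtype and 0.162 FPKM in hairloss skin, and Krt81 at 1.18 and 0.325 FPKM. Among the 57 KRTAPs, Krtap7-1 and Krtap8-1 were at least 2-fold lower in the hairloss library, at levels under 4 FPKM in both genotypes.

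By the size rule of 2-fold on that scale, 249 genes were higher and 263 lower in the hairloss library among 16685 genes compared at day 0. Restricted to protein-coding genes, the counts were 65 higher and 64 lower, so most of these genes were noncoding. The fixed size rule has no test behind it and covers these libraries alone.

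At day 16 hair shaft genes were lower and wound-type epidermal genes higher in the hairloss library. Krt31 (chromosome 11, 100046646 to 100050551), a hair shaft keratin, stood at 313 FPKM in wildtype and 80.7 FPKM in hairloss skin, and Krt86 (chromosome 15, 101473478 to 101479986) at 710 and 143.5 FPKM. Of the 15 hair shaft keratins, 13 were at least 2-fold lower and 0 higher, with a median difference of -2.04 at percentile 0. Of the 57 KRTAPs, 53 were lower, and Krtap5-2 alone was higher, with a median of -2.26. Krtap8-1 (chromosome 16, 89487379 to 89487952) stood at 5004 and 722 FPKM, and Krtap15 at 1222 and 28.9 FPKM. Members of KRTAP subfamilies are near-identical in sequence, so values of single KRTAPs are uncertain.

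The inner root sheath, the layer that moulds the growing shaft, had 8 of 13 genes at least 2-fold lower at day 16, with a median of -1.48. Krt72 stood at 1092 and 174 FPKM and Krt28 at 1014 and 174 FPKM, while Krt71 (2666 and 1903 FPKM) and Krt25 (1505 and 1339 FPKM) lay within 2-fold. Trichohyalin (Tchh) was the exception, listed at 0 in wildtype and at 1419 FPKM in hairloss skin. Regulators and markers of the hair matrix had a median of -0.93, with 12 of 26 genes lower and 0 higher. Among them Gprc5d stood at 365 and 75.3 FPKM, Crym at 527 and 75.1 FPKM, and Dlx3, a homeobox factor of the hair matrix, at 97.7 and 27.2 FPKM.

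Alarmins and wound-type epidermal genes had a median difference of 3.68 at day 16, with 13 of 16 members higher and only Sprr2h lower. Stefin A3 (Stfa3; chromosome 16, 36450537 to 36455392), a cysteine protease inhibitor, stood at 15.3 FPKM in wildtype and 8940 FPKM in hairloss skin. S100a9 (chromosome 3, 90692632 to 90695721) and S100a8, the subunits of calprotectin, stood at 16.6 and 1748 FPKM and at 134 and 1984 FPKM. Krt6b stood at 0.229 and 570 FPKM, and Krt16 at 16.9 and 614 FPKM. The stefin A genes are near-identical copies, so their single values are uncertain. Small proline-rich genes had a median of 1.30 and late cornified envelope genes of 1.63, with 15 of 21 of the latter higher and Lce1m alone lower.

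Markers of neutrophils, macrophages and mast cells stood higher in the same day 16 library. All 10 neutrophil genes were at least 2-fold higher, with a median of 2.53, although S100a8 and S100a9 are also members of the alarm list. The neutrophil receptors Cxcr2 and Csf3r stood at 0.269 and 7.58 FPKM and at 0.158 and 7.38 FPKM. All 14 macrophage genes were higher, with a median of 1.53, as in Ctss at 20.2 and 117 FPKM. Mast cell genes had a median of 1.04 with 5 of 9 higher, and inflammatory cytokines and chemokines one of 1.01 with 8 of 14 higher, among them Cxcl5 at 0.0432 and 12.4 FPKM and Ccl20 at 0.909 and 21.1 FPKM. T cell genes went both ways, with a median of 0.09 and 3 of 12 past 2-fold, namely Gzmb, Cd4 and Il2rb, while the T cell receptor subunit gene Cd3g stood at 9.87 and 5.15 FPKM and Cd3e at 1.87 and 0.589 FPKM. Adult skeletal muscle genes were lower, with a median of -0.80 and 8 of 21 past 2-fold. In all, 864 genes were higher and 1196 lower among 16186 compared, of which 709 and 667 were protein-coding.

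At day 19 the order of the hair genes was the opposite, a difference between days that was not tested. Krt31 stood at 0.915 FPKM in wildtype and 33.3 FPKM in hairloss skin, Krt71 at 28.6 and 542 FPKM, and Krtap8-1 at 33.4 and 262 FPKM. Of the 15 hair shaft keratins 13 were at least 2-fold higher and 0 lower, with a median of 3.34 at percentile 100. Of the 57 KRTAPs 49 were higher and 0 lower, with a median of 2.43, and of 13 inner root sheath genes 11 were higher and 0 lower, with a median of 3.61. Hair matrix genes had a median of 0.95 with 11 of 26 higher, as in S100a3 at 7.93 and 191 FPKM. Cell cycle genes had a median of 1.08, with 16 of 27 higher and 0 lower, among them Mki67 at 6.06 and 18.5 FPKM and Cdk1 at 6.91 and 21.4 FPKM.

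The alarm list had its highest median at day 19, 5.15, with 15 of 16 members higher and 0 lower. Stfa3 stood at 12.6 FPKM in wildtype and 10770 FPKM in hairloss skin, S100a9 at 3.23 and 3004 FPKM, S100a8 at 7.64 and 3499 FPKM, and Krt6b at 0.236 and 833 FPKM. Krt14, the keratin of basal keratinocytes, stood at 618 and 4829 FPKM, and Krt1, of the suprabasal layers, at 218 and 2541 FPKM. Going the other way, the suprabasal keratin Krt77 stood at 1109 and 10.9 FPKM and Lce1m at 381 and 18.7 FPKM, although 12 of 21 late cornified envelope genes were higher. Neutrophil genes had a median of 1.79 with 8 of 10 higher. Macrophage genes had a median of 0.09, which turned to -0.02 when libraries were scaled without keratins and KRTAPs. Adult muscle genes were lower, with 15 of 21 past 2-fold and a median of -1.09, and 4 of 6 erythroid genes were lower, the globin gene Hbb-bs standing at 580 and 154 FPKM. Markers of other tissues outside the epidermis lay lower too, with medians of -0.95 for adipocyte genes (8 of 19 past 2-fold, percentile 0), -0.82 for endothelial, -0.74 for Schwann cell and nerve and -0.70 for dermal matrix genes. In all, 1088 genes were higher and 960 lower among 16656 compared. With libraries scaled without keratins and KRTAPs the split was 988 higher and 1146 lower, and with a pseudocount of 0.1 it was 1519 and 1554, so which direction held more genes depends on both choices.

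At day 28 hair shaft genes were lower in the hairloss library, several of them close to undetected. Krt31 stood at 343 FPKM in wildtype and 0.0273 FPKM in hairloss skin, Krt86 at 504 and 0.0211 FPKM, Krtap8-1 at 3634 and 0.0734 FPKM, and Krtap22-2 at 3914 and 1.23 FPKM. Krt35 stood apart from these at 309 and 12.7 FPKM. All 15 hair shaft keratins and all 57 KRTAPs were at least 2-fold lower, and 39 of the KRTAPs were listed at 0 in the hairloss library. The medians were -8.35 and -7.09, values that depend on the pseudocount because hairloss levels lay near 0. For KRTAPs the median was -10.25 with a pseudocount of 0.1 and -4.81 with one of 5. Inner root sheath genes had a median of -4.95 with 12 of 13 lower, yet Krt71 and Krt25 remained measurable at 78.7 and 87.7 FPKM in hairloss skin, against 2466 and 1643 FPKM in wildtype. Hair matrix genes had a median of -1.78 with 16 of 26 lower and 0 higher, among them desmoglein 4 (Dsg4), an adhesion protein of the hair shaft, at 61.3 and 0.750 FPKM. Pigment cell genes had a median of -1.87 with 12 of 14 lower, as in tyrosinase (Tyr), which starts melanin synthesis, at 23.8 and 5.78 FPKM and Mlana at 75.4 and 8.76 FPKM.

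Late cornified envelope and alarm genes stood higher in the day 28 hairloss library, while other epidermal lists were mixed. Of 21 late cornified envelope genes 20 were at least 2-fold higher, with a median of 3.0, and the alarm list had a median of 2.49 with 13 of 16 higher and 0 lower. Other cornified envelope genes had a median of 0.78 with 9 of 23 higher and 2 lower, and epidermal keratins one of 0.235 with 5 of 14 higher and 2 lower. Krt1 stood at 82.1 and 2623 FPKM, Krt10 at 407 and 3251 FPKM, Stfa3 at 45.9 and 3978 FPKM, and Slurp2 at 1.57 and 152.5 FPKM. Mast cell genes had a median of 1.85 with 8 of 9 higher, and adult muscle genes one of 1.31 with 18 of 21 higher, and adipocyte, endothelial, Schwann cell and nerve, and dermal matrix genes had medians of 0.60, 0.78, 0.66 and 0.51, opposite in sign to those of day 19. Cell cycle genes had a median of 0.05 with 0 of 27 past 2-fold, and of the neutrophil genes only S100a8, S100a9 and Cxcr2 of 10 were past 2-fold. In all, 897 genes were higher and 1029 lower among 16021 compared. With libraries scaled without keratins and KRTAPs the split was 1087 higher and 898 lower, and the median of all genes was then 0.11 instead of 0. With a pseudocount of 0.1 the split was 1424 higher and 1401 lower.

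**Figure D2:**
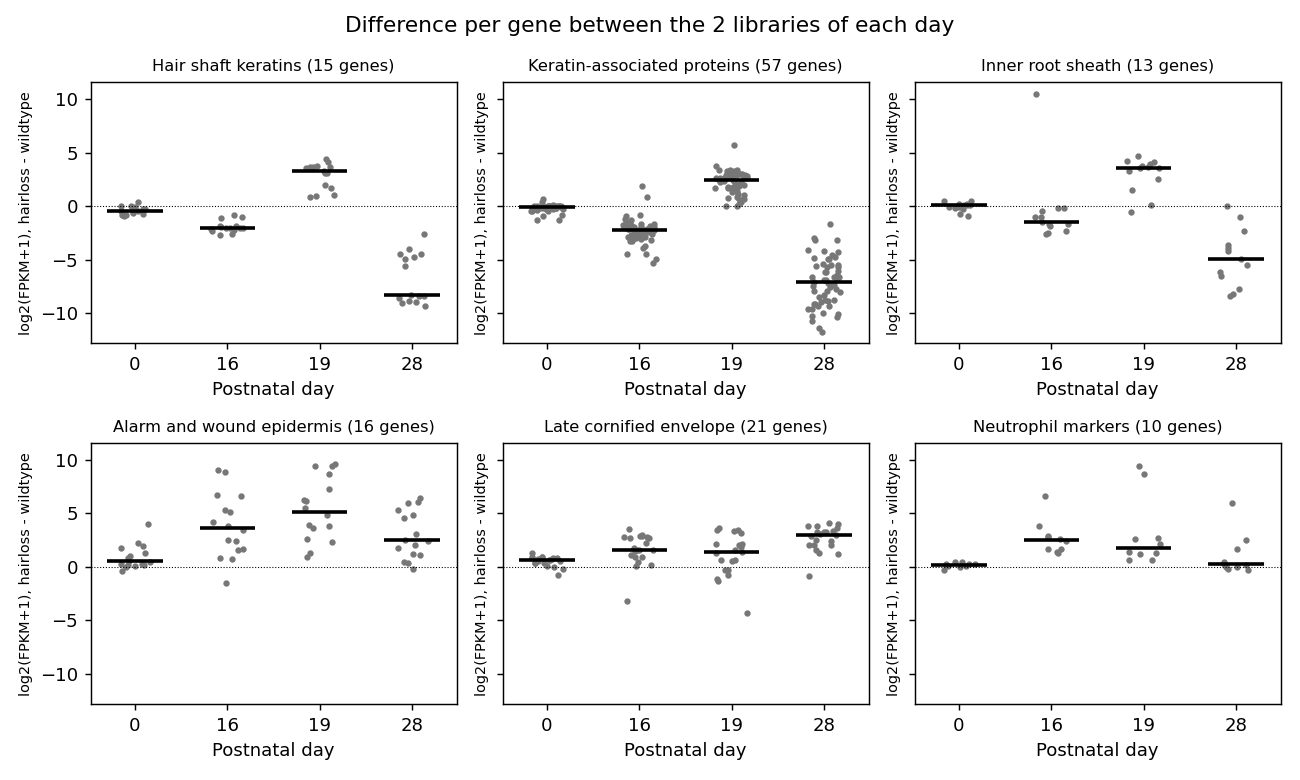
Difference per gene between the hairloss and the wildtype library of each postnatal day, on the log2(FPKM + 1) scale, with days spaced evenly; each grey point is a gene of the list and each black bar the list's median. Hair shaft keratins had medians of -2.04, 3.34 and -8.35 at days 16, 19 and 28, and the highest point of the inner root sheath list at day 16 is Tchh, listed at 0 in wildtype.

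Of 43 genes in which mutations cause hair loss in mice, a list fixed without reference to these samples, 11 were at least 2-fold lower and 3 higher at day 16, 16 higher and 1 lower at day 19, and 19 lower and 3 higher at day 28. The medians were -0.25, 0.77 and -0.61, and -0.01 at day 0. Dsg4 stood at 2.29 FPKM in wildtype and 1.51 FPKM in hairloss skin at day 0, at 79.6 and 23.1 FPKM at day 16, and at 2.35 and 10.03 FPKM at day 19. Hr, the transcriptional corepressor hairless, stood at 24.7 and 37.8 FPKM at day 0, 156 and 145 FPKM at day 16, 79.2 and 159.5 FPKM at day 19, and 48.7 and 60.9 FPKM at day 28. Msx2, a homeobox factor of the hair matrix, stood at 31.4 and 8.26 FPKM at day 16 and at 35.9 and 3.64 FPKM at day 28. The 3 higher at day 16 were Gsdma3, Ctsl and Elovl3, the 1 lower at day 19 was Soat1, and the 3 higher at day 28 were Soat1, Scd1 and Elovl3. The labels do not say which gene is mutated.

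Taken as 4 pairs of equal age, the libraries allowed a test of the genotype difference against its spread over ages. Among protein-coding genes higher in hairloss at all 4 ages, Krt6b had the largest mean difference, 7.08 ± 1.09 (SE, 4 ages), followed by Stfa3 at 6.61 ± 1.64, Cstdc5 at 5.94 ± 1.69 and S100a9 at 5.58 ± 1.67. Among genes lower at all 4 ages, Hamp2, a hepcidin, had a mean difference of -5.08 ± 1.55, Serpina3b one of -3.05 ± 0.80 and Dapl1, an epithelial differentiation gene, one of -2.75 ± 0.26. None of these passed the threshold after Benjamini-Hochberg adjustment over 18724 genes with limma, the adjusted p being 0.304 for Krt6b, 0.349 for Hamp2 and 0.147 for Dapl1. The genes that passed in coding or polymorphic loci were Sprr2g (chromosome 3, 92373915 to 92375229, annotated as a polymorphic pseudogene), which was higher by 2.49 ± 0.13 (SE, 4 ages; limma adjusted p = 0.0253), and Grhl3 (chromosome 4, 135541888 to 135573630), a transcription factor of epidermal barrier formation, which was higher by 1.39 ± 0.10 (limma adjusted p = 0.0461). Grhl3 stood at 6.07, 12.6, 15.8 and 11.2 FPKM in wildtype and at 15.7, 35.9, 42.3 and 34.0 FPKM in hairloss skin at days 0, 16, 19 and 28. Leaving out an age in turn raised the adjusted p to as much as 0.199 for Sprr2g and 0.454 for Grhl3, and ended both calls in each of the 4 fits. These fits have fewer residual degrees of freedom than the 3 of the full fit, so a lost call need not mean that the difference rests on that age.

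In all, 7 genes passed, 5 higher and 2 lower, against 2511 at an unadjusted p under 0.05. The other 5, named here after their values were seen, were short noncoding genes and a processed pseudogene, each listed at 0 in all 4 libraries of one genotype. The small nucleolar RNA gene Snord47, which lies inside Gas5, was listed at 0 in every wildtype library and at 8873 to 29500 FPKM in the hairloss libraries, and it was the only one to pass in each of the 4 fits without an age. Snord33, inside Rpl13a, and the pseudogene Gm45660 were likewise listed at 0 in wildtype only, and Gm25989 and Gm27271 in hairloss only. The host genes Gas5 and Rpl13a had mean differences of -0.23 and -0.33 (limma adjusted p = 0.531 and 0.534). Reads of genes nested in a host cannot be assigned to either with certainty. With protein-coding genes alone, with suspected failed estimates left out, or without days 0 and 28, 0 genes passed. Both of the first settings remove these 5 genes by construction, and the last leaves fewer residual degrees of freedom. Sprr2g and Grhl3 are not among the suspected failed estimates, yet both lost their calls when those were left out. Their calls in the full fit therefore depend on suspected failed estimates being kept among the genes adjusted together. At all 4 ages 2159 genes were higher and 2531 lower, 25% of those tested, where independent signs would give 12.5%. That excess was not tested, as genes vary together within a library, and sex markers also differed at days 0, 19 and 28. Protein-coding genes 2-fold apart in 1 direction at all 4 ages numbered 18 higher and 6 lower.

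Over the 4 ages, 18 of 49 gene lists passed by camera with a preset correlation of 0.01, 13 higher in hairloss skin relative to other genes and 5 lower. With an estimated correlation 0 of 49 lists passed, the lowest being adjusted p = 0.880 with an estimated correlation. The alarm list (adjusted p = 2.39e-11), late cornified envelope genes (7.46e-11), small proline-rich genes (8.59e-07), cell cycle genes (2.85e-06), basement membrane genes (2.85e-06), neutrophil genes (8.11e-06) and mast cell genes (5.99e-05) were among the higher ones. So was the control list of housekeeping genes (0.00193), with medians of 0.05, 0.39, 0.53 and 0.19 at days 0, 16, 19 and 28. The 5 lower ones were KRTAPs (6.32e-05), their high-sulfur, ultrahigh-sulfur and high glycine-tyrosine members, and pigment cell genes (0.00219). The KRTAP subfamilies are parts of the full KRTAP list and not separate calls. Some of the higher lists share members too, as the alarm list does with the companion layer and outer root sheath list. The cell cycle list had medians of 0.59 and 1.08 at days 16 and 19 but of -0.15 and 0.05 at days 0 and 28, and 6 of its 27 genes were higher at all 4 ages. Mast cell genes had medians of 0.06 and -0.26 at days 0 and 19, where 0 and 1 of 9 were past 2-fold. Neutrophil genes had medians of 0.21 and 0.25 at days 0 and 28. The directional fry test passed 0 lists, and its mixed form passed the small proline-rich genes alone (adjusted p = 0.0250). The KRTAP call was lost and its direction turned without day 28 (adjusted p = 0.808), as its medians had opposite signs at days 19 and 28. The pigment cell call was lost without days 0 and 28 (adjusted p = 0.104), against 0.000577 to 0.0241 with 1 age left out, and the list medians were -0.28, -0.27, -0.08 and -1.87 at days 0, 16, 19 and 28.

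Counted within the lists, 12 of 16 alarm genes passed higher when adjusted over the list alone, among them Krt6b, Krt16, Stfa3 and S100a9, and 0 passed over all genes. Adjustment over a list alone does not cover the number of lists tested. Alarm genes also varied together (estimated correlation 0.653), so their calls are not separate evidence. Of the late cornified envelope genes 15 passed higher and Lce1m lower when adjusted over the list alone, and 0 over all genes. Of the small proline-rich genes 6 passed higher and Sprr4 lower when adjusted over the list alone, and 1 over all genes. Of 9 companion layer and outer root sheath genes 5 passed higher when adjusted over the list alone, namely Krt5, Krt6a, Krt6b, Krt14 and Krt16, and 0 over all genes. Krt6a, Krt6b and Krt16 are alarm genes too and are counted in both lists. Of the basement membrane genes 6 of 11 passed higher when adjusted over the list alone, among them the integrin gene Itga6 and the laminin gene Lama3, and 0 over all genes. No hair shaft keratin and no KRTAP passed in either way. Where a list's median and the direction of its camera test differed in sign, as for adipocyte genes, the list did not pass.

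With genotype as a block, the age steps tested what the genotypes had in common. Between days 0 and 16 the beta-defensin gene Defb6 rose by 9.93 ± 0.40 (SE, 2 genotypes; limma adjusted p = 0.00283), the cystatin Cst6 by 6.57 ± 0.33 (limma adjusted p = 0.00526), the chemokine Ccl8 by 7.06 and Sprr4 by 6.79. Of 12 genes of developing muscle 9 fell and 0 rose past the threshold, with median steps of -2.28 in wildtype and -2.57 in hairloss skin. The largest of these falls were in embryonic and perinatal myosin genes, where Myh8 fell by 7.25 ± 0.28 and Myh3 fell by 6.44 ± 0.24 (limma adjusted p = 0.00283 for each), and Myl4 fell by 4.74. In all 670 genes rose and 827 fell. Without a filter on low values 168 rose and 288 fell, and with libraries scaled without keratins and KRTAPs 590 rose and 1723 fell. With a filter at 5 the counts were 665 and 513, and with a pseudocount of 0.1 838 and 796, so which direction held more genes depends on these choices.

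Between days 16 and 19 hair shaft keratins had a median step of -6.93 in wildtype and -1.27 in hairloss skin, and KRTAPs one of -5.99 and -1.16. Between days 19 and 28 the steps were 6.88 and -4.80 for hair shaft keratins, and 5.56 and -3.86 for KRTAPs. Pigment cell genes had steps of 3.24 and 1.25 between days 19 and 28, and cell cycle genes of 2.19 and 1.03. The limma test of the day 19 step passed 3 genes, named here after their values were seen: Gm24950 higher, and Gm23445 and Gm26444 lower. Gm24950 was listed at 0 in all 4 libraries of days 0 and 16 and at 10.2 to 14.3 FPKM in the others, and Gm23445 and Gm26444 were listed at 0 at every age but day 16, so these calls rest on values that can be failed estimates. The day 28 step passed 0 genes with limma, against 1910 at an unadjusted p under 0.05. The genotypes' steps were not tested against each other, since each rests on 1 library per age.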

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

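Among the tests below, those of library scaling, swapped labels, hair-cycle position and sex were chosen only after the result was seen, as was the 2-fold bound that a list median had to pass in opposite directions. At 2-fold or more, 7 of 49 lists had medians of opposite sign at different ages, and at any size 23 did. Hair shaft keratins had medians of -2.04, 3.34 and -8.35 (hairloss minus wildtype, log2 of FPKM + 1) at days 16, 19 and 28. Inner root sheath genes had medians of -1.48, 3.61 and -4.95. KRTAPs had medians of -2.26, 2.43 and -7.09, their high-sulfur members -2.05, 2.74 and -7.23, their ultrahigh-sulfur members -2.15, 2.19 and -5.63, and their high glycine-tyrosine members -2.49, 2.71 and -9.18. The 3 KRTAP subfamilies are parts of the full KRTAP list and not separate evidence. Adult skeletal muscle genes had medians of -1.09 at day 19 and 1.31 at day 28. With 1 library per group, these differences between ages were not tested.

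With libraries scaled on coding genes outside the keratin and KRTAP families, the KRTAP medians were -2.25, 2.37 and -6.98 at days 16, 19 and 28. The log2 factors of that scaling at day 28 were 0.1085 in wildtype and -0.0153 in hairloss, so it could not have moved the median far. It speaks only to the share that these families take of a library, and other errors of scaling were not tested. For the hair keratins and KRTAPs, swapped genotype labels at 1 age are argued against as the whole cause by coding genes apart by 2-fold at the other 3 ages. Those genes kept their direction in at least 75.7% of cases (28 of 37 at day 19, exact 95% interval 58.8% to 88.2%). The interval takes genes of the same libraries as independent draws, which they are not, so it can be too narrow. Sex as the whole cause is argued against at day 16, where sex markers matched and the KRTAP median was -2.26, and at day 19, where Y-linked RNA in wildtype reached at least 0.759 of the hairloss level, so that a mixture of sexes alone allows a difference of at most 0.40 against the median of 2.43. At day 28 sex cannot be told apart from genotype, because the libraries shared no sex marker and the median of -7.09 has no pair of equal sex beside it. A candidate explanation is another point of the hair cycle, since on 158 genes outside the keratins, KRTAPs and fixed lists, scaled from 0 (wildtype day 19) to 1 (mean of wildtype days 16 and 28), hairloss libraries lay at 0.602, 0.389 and 0.001 at days 16, 19 and 28. It cannot be told apart from partial loss of follicles or the mutation's own effect. At day 28 other values go against the wildtype day 19 stage or an absence of follicles. Shh stood at 3.61 FPKM in wildtype and 3.27 FPKM in hairloss skin (0.0261 FPKM in wildtype at day 19), Wif1 at 17.4 and 14.2 FPKM and Gli1 at 8.63 and 16.8 FPKM. Between wildtype days 19 (0) and 28 (1), hairloss hedgehog genes lay at 1.32. Hairloss cell cycle genes lay at 0.962 on that scale, but they are not particular to follicles, so this value cannot tell whether follicles were present.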

How the results depend on the processing

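The fits without days 0 and 28, those on coding or autosomal genes only, and those with suspected failed estimates left out were chosen after seeing the data. Where a value changed and its construction shows no reason, the cause was not tested. The medians of alarm and inner root sheath genes kept their direction at each age, between 0.34 and 5.80 for alarm genes. With a pseudocount of 0.1, which widens differences of low genes, genes 2-fold apart numbered 883, 3505 and 3073 at days 0, 16 and 19. With one of 5, which narrows them, they numbered 213, 898, 903 and 968 at days 0, 16, 19 and 28. At 4-fold there were 172, 517, 513 and 601. At day 0 a filter at 5 left 271 and coding genes alone 129. Having no filter changed none of these counts, as the size rule already asks for 1 FPKM, and so tests nothing there. At a pseudocount of 0.1 the median of hair shaft keratins at day 0 was -0.921, and that of KRTAPs was -0.550 at day 0 and -10.249 at day 28, against -4.812 at day 28 with 5. Genes past the genotype threshold numbered 3 with a pseudocount of 5, 2 without a filter, and 0 with coding genes, with failed estimates left out or without days 0 and 28, and 1 to 5 with an age left out, the lowest without day 28 and 2 without day 16. Gene lists numbered 0 with an estimated correlation and 18 to 30 with an age left out, the highest without day 19. The day 16 step had 456 genes without a filter and 2313 when scaled without keratins and KRTAPs. The day 19 step had 1 with a pseudocount of 5, 1 without a filter, 1 with a filter at 5 and 0 with coding genes, and the day 28 step 5 with a pseudocount of 0.1. Leaving out an age gave camera adjusted p of 1.8e-10 to 0.808 for KRTAPs, 0.000167 to 0.857 for high-sulfur, 3.14e-05 to 0.772 for ultrahigh-sulfur and 0.000146 to 0.826 for high glycine-tyrosine KRTAPs, the direction turning without day 28, the age of the largest difference. Without days 0 and 28 it turned too (0.645, 0.698, 0.631 and 0.660). Of all alternative list medians, 1321 stayed within the spread of their members and 35 moved. That yardstick is wide, as a change of sign like that of macrophage genes at day 19 lies within it. Some alternatives also left a list's members and values untouched, so the count overstates stability. Of all alternative adjusted p of lists, 378 kept their side of the threshold, 31 gained it, 24 lost it and 8 turned, and of those of Sprr2g and Grhl3 9 kept it and 20 lost it. Of named single genes 317 kept the size rule and 3 lost it, a count that was nearly assured because these genes were chosen for the largest differences. No paired analysis by replicate number was possible because each group holds 1 library. The alternatives for counts and transcripts were not run, since the files hold 1 FPKM value per gene. Depth limits differences under about 0.095 FPKM in a transcript of 1 kb.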

Other observations

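The tests reported here of neutrophil RNA, epidermal share, sex, T cell genes and splits by gene count were chosen only after the results were seen, while the count of splits for lists was planned before. Hamp2 stood at 134 FPKM in wildtype and 0.278 FPKM in hairloss skin at day 16, and at 368 FPKM against a value listed at 0 at day 19. Cyp2g1, a cytochrome P450 of olfactory and other epithelia, stood at 65.1 and 1.91 FPKM at day 16, at 142 and 0.371 FPKM at day 19, and at 0.491 and 4.20 FPKM at day 28. Serpina3b stood at 26.4 and 1.15 FPKM, 66.8 and 0.579 FPKM, and 48.0 and 10.2 FPKM at days 16, 19 and 28. Cyp1a1, the aryl hydrocarbon receptor target, stood at 37.1 and 140 FPKM at day 16, 105 and 88.0 FPKM at day 19, and 4.05 and 308 FPKM at day 28. The RNA components of RNase MRP and RNase P, Rmrp and Rpph1, were lower in hairloss at all 4 ages, with mean differences of -2.50 ± 0.37 and -2.29 ± 0.26 (SE, 4 ages; limma adjusted p = 0.295 and 0.240). Neither difference passed, and both are short noncoding RNAs, whose FPKM values are unstable. At day 0 brown fat genes had a median difference of -0.78, with 2 of 7 lower.

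Over 14189 coding genes, the hairloss library of day 19 lay nearer to the wildtype library of day 16 than to that of its own age, with a median absolute log2 difference of 0.271 against 0.319. At day 28 the measures were split, the median absolute difference being smaller to wildtype day 28 (0.273) than to wildtype day 19 (0.294), and Pearson's r across genes lower (0.906 against 0.936). Genes are not independent replicates, and these values describe the libraries.

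The alarm list was higher in hairloss skin at days 16, 19 and 28, together with neutrophil genes at days 16 and 19, whereas at day 28 the neutrophil median was 0.25. Neutrophil RNA is argued against as the whole cause, because 5 keratin and Sprr members of the list, which neutrophils lack, had medians of 2.56, 5.47 and 2.08 at these ages, leaving out Sprr2d, which was listed at 0 in wildtype at each of them. Sex as the whole cause is argued against at day 16, where the sex markers matched and the list median was 3.68, and at day 19, where the list median of 5.15 exceeded the 0.40 that the mixture of sexes allows, but at day 28 (2.49) it cannot be told apart from genotype, as the libraries shared no sex marker. A larger share of epidermis in the hairloss samples cannot be told apart from a change within the epidermis, since the alarm median, taken over the 15 members other than Sprr2d, exceeded the epidermal keratin median by 3.11, 4.36 and 2.19 but the 95% intervals over resampled members began at 0.01, 1.64 and 0.19. Markers outside the epidermis went both ways, with medians at days 19 and 28 of -1.09 and 1.31 for adult muscle genes and -0.82 and 0.78 for endothelial genes. A larger epidermal share would lower such markers, as at day 19 but not at day 28. A wound-type state of the epidermis is a hypothesis that stays open beside a larger epidermal share.

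Tcrg-V5 (chromosome 13, 19192278 to 19192725), the variable segment carried by dendritic epidermal T cells, was singled out after its values were seen, and its mean difference of -1.80 ± 0.25 (SE, 4 ages) did not pass (limma adjusted p = 0.295). It stood at 1.04, 3.92, 5.02 and 2.16 FPKM in wildtype at days 0, 16, 19 and 28, and in hairloss skin at 0.313 FPKM at day 19 and listed at 0 at the other ages. Fewer of these cells in hairloss skin is a candidate explanation: of 9 other genes written down for them, 5 of which are also in the T cell list, 6 were lower at all 4 ages, against 13.5% of all genes, with Trdv4 at 10.9 and 2.07 FPKM at day 16 and 18.3 and 0.874 FPKM at day 19. Il2rb, Xcl1 and Klrd1 were not, and lower transcription of the receptor genes in as many cells would look alike. Some of the gaps were small: Trdc stood at 0.0997 and 0.0658 FPKM at day 0, near the floor, and Tcrg-C1 at 0.986 and 0.922 FPKM at day 28. Genes of the same cells also vary together, so the 6 are not independent draws to set against the share of all genes. Of 11 measured Skint genes, whose founding member selects these cells, 5 were lower at all 4 ages, with medians of -0.46, -0.75, -2.19 and 0.54 at days 0, 16, 19 and 28.

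Other splits of the 8 libraries into groups of 4 bear on the tests over ages. Of 35 splits 32 could be fitted, and 7 of them, the real one included, gave at least the 7 genes of the real split, so chance cannot be excluded on that count. Of the 32, 24 part the libraries of only 2 ages and fall into pairs that the age block makes 1 and the same fit. With each fit counted once, 4 of 20 gave as many genes as the real one, again by the genotype difference at all or part of the ages. As many lists as in the real one came from 15 of 20. The highest other split gave 33 genes, several times the real count. With age as a block, that split compares the genotypes at days 16 and 28 alone. Its count therefore does not point to a structure among the samples apart from genotype. Among the 8 splits that part the genotypes within every age the real one gave 7 and the highest other 1. Yet 8 splits are too few for a share under 0.05, so chance was not excluded for the number of genes. For gene lists 24 of 32 splits gave at least the 18 lists of the real one, the highest other gave 32, and 6 of the 8 splits within ages gave as many, so chance cannot be excluded for the number of lists.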
